A study of Mus musculus with 4 samples.

How the data were processed

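Total RNA of mouse olfactory bulbs at postnatal day 11 was sequenced in 4 libraries, 2 from littermate controls without Cre and 2 from DCKO mice (Sp8 Flox/Flox and Sp9 Flox/Flox, with the Dlx5/6-CIE transgene) on a mixed C57BL/6J, 129S6 and CD1 background. Per the labels' protocols, bulbs were dissected in cold buffer and frozen, RNA was purified with RNeasy kits, RNA integrity was checked, and libraries were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were processed with TopHat (version not given) and Cufflinks 2.1.1 against GRCm38.p4. The annotation, the aligner settings and the strand setting are not given in the sources used here. The deposited table lists 20032 genes by symbol with 2 kinds of values per library. The FPKM columns, per the file headers, were made by the authors and scale fragments by transcript length and by mapped fragments. The columns headed count are treated here as a signal that the authors scaled: estimated fragment counts multiplied by 1 factor per library, since 98.7% to 98.9% of the values above 0 lie within 0.05 of whole multiples of a step that differs between libraries. Because these values are not raw counts, no count model was applied.

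The scaled counts sum to 15033308 and 15400982 in controls 1 and 2 and to 14899179 and 14632502 in DCKO 1 and 2. Because of the scaling these sums are close to the depth and not equal to it. Genes with a value above 0 number 18356, 17533, 17768 and 17720 in the same order, and the FPKM values sum to 344704, 345365, 345143 and 351233. Each column was mapped to its sample by the code that the sample descriptions give, and 0 columns of per-sample values were left unmapped.

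The comparison is DCKO minus control, fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the empirical Bayes step. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 13434 in all, two-sided, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale unless a ratio of mean FPKM is given, and this scale understates the change of genes with low values. The prior degrees of freedom of the fit were 2.91, and the median log2 change over all tested genes was -0.0157. At an unadjusted p below 0.05, 5790 genes pass. Symbols were matched to GENCODE M21 for coordinates and biotypes, with 19717 of 20032 (98.4%) matched to 1 gene, 967 of them through an older symbol, and 24 symbols in the file look like dates.

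Of 30 gene lists fixed from general knowledge, 29 had at least 3 members past the filter and were tested, 8 of them as primary lists on bulb neurons. Some genes sit in 2 lists, among them Gfap, Npy, Pax6, Reln and Sox10. For each list, members past the threshold were counted over all genes and again with p adjusted over the list alone. The set test was camera with a preset correlation between genes of 0.01, adjusted over the 29 lists, which asks whether the members changed more than other genes did. Camera with a correlation estimated from the 4 libraries and fry, which asks whether the members moved on balance one way without comparing them with other genes, were alternatives. The design, the lists, the rule for named genes and all alternatives except those on scaled counts and without chromosomes X and Y were fixed before the data were examined.

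Genes are named by rule, beginning with Sp8 and Sp9. The rule adds the 12 called genes of largest change in each direction whose groups do not overlap, leaving out clone, predicted and numeric symbols. It takes up to 4 called members of each list with the largest change, or the 2 members of highest mean where none was called, and Prokr2, Tshz1, Robo1, Th, Calb1, Calb2, Pvalb, Gad1, Slc17a7, Tbx21 and Dcx whatever their values. Members of short lists that go against their list or did not pass are named outside this rule, as are Bpifa1, Col1a1, Ibsp and the genes that open the other observations; these were chosen after their values were seen. Genes with near-identical copies, overlapping genes and antisense genes are uncertain, since the counting of shared reads and the strand setting are not given in the sources used here.

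The model was tested on simulated data made from the same 13434 genes, with 200 genes changed. It recovered 89% of the genes changed by 1 on the log2 scale and 98% of those changed by 2, and 16 of its 203 calls (7.88%) were false. With no gene changed it made 1 call. The simulation drew independent errors from the fitted variance model and changed only genes with a mean log2(FPKM + 1) above 2. It met the assumptions of the test by design, so these rates do not measure how well the test did on the real libraries. Alternatives covered the pseudocount, the filter, 3 other scalings between libraries, the variance trend, a replicate block, each library left out in turn, the scaled counts and the exclusion of chromosomes X and Y.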

Results

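RNA sequencing was used to ask how gene expression in the mouse olfactory bulb differs when Sp8 and Sp9 are both removed from the interneuron lineage. Sp8 and Sp9 are zinc finger transcription factors of the Sp family. The olfactory bulb is the first relay of odour information in the brain, and most of its neurons are GABAergic interneurons, the granule and periglomerular cells, which are born outside the bulb and migrate into it as neuroblasts. The mutants, called DCKO here for double conditional knockout, carried floxed alleles of both genes and the Dlx5/6-CIE transgene, which places Cre recombinase under a Dlx5/6 enhancer active in GABAergic precursors. Bulbs of 2 DCKO samples and 2 littermate controls without Cre were collected at postnatal day 11, giving 4 libraries. The labels do not say whether the replicates of a genotype came from separate animals. Xist and the Y-linked genes, given below, show that the DCKO libraries did, and for the controls this stays open. The p-values measure the spread between these samples. The deposited scaled fragment counts summed to 15033308 and 15400982 in control replicates 1 and 2 and to 14899179 and 14632502 in DCKO replicates 1 and 2. Across the 13434 tested genes, the Pearson correlation of log2 values was 0.982 between the controls and 0.986 between the DCKO libraries, against 0.932 to 0.944 for the 4 pairs that cross genotypes. These correlations are across genes, which are not independent replicates.

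Both targeted genes were low in both DCKO libraries. Sp8 (chromosome 12, 118846329 to 118852576, GRCm38, a protein-coding gene on the + strand) stood at 32.0 and 26.7 FPKM in the controls and 1.68 and 2.03 FPKM in DCKO, a 15.8-fold lower mean. The log2 change was -3.41 (SE 0.12, 95% confidence interval -3.72 to -3.09, limma adjusted p = 0.000744). Sp9 (chromosome 2, 73271925 to 73284706, + strand, protein-coding) stood at 24.0 and 30.7 FPKM in the controls and 0.0674 and 0.236 FPKM in DCKO. Its log2 change was -4.62 (SE 0.15, 95% confidence interval -5.01 to -4.22, limma adjusted p = 0.000709), a 180.5-fold lower mean. Sp9 overlaps the gene Cir1 on the - strand, which did not pass the test (log2 change -0.09). The FPKM values cover whole gene models, so they do not separate the floxed exons from the remaining ones. Among the other Sp family members, 2 of 6 measured genes fell and none rose, the same count adjusted over the list alone. Sp7, a transcription factor best known from bone formation, fell from 12.9 ± 1.73 to 0.377 ± 0.0609 FPKM (SD, n = 2 per group, log2 change -3.33, limma adjusted p = 0.000745). Sp4 fell from 7.65 ± 0.196 to 4.76 ± 0.637 FPKM (log2 change -0.59, adjusted p = 0.0202). The Sp4 call was lost without control replicate 1 (adjusted p = 0.0541) and without control replicate 2 (adjusted p = 0.0782). Sp1, Sp2, Sp3 and Sp5 did not pass the test, and the list as a set did not either (camera adjusted p = 0.146).

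Genes of inhibitory interneurons and neuronal activity were lower in the DCKO bulbs, and genes of projection neurons, astrocytes, microglia and dividing cells were higher. All 8 measured granule cell markers, all 5 genes of GABA synthesis and transport, 12 of 15 interneuron transcription factors and 11 of 12 immediate early genes fell. In contrast, 8 of 10 mitral and tufted cell markers, 9 of 11 cell cycle genes, 7 of 12 astrocyte markers and 9 of 12 microglia markers rose. In the limma test, 1926 of 13434 tested genes fell and 1747 rose in DCKO at an adjusted p below 0.05. Large decreases outnumbered large increases: 410 genes fell by at least 1 on the log2 scale and 158 rose by that much, and at a log2 change of at least 2 there were 100 lower and 7 higher genes. Besides Sp9, the largest decreases by the rule for named genes were in Frmd7, a FERM-domain protein (27.5 to 0.154 FPKM, log2 change -4.63), Th, the rate-limiting enzyme of dopamine synthesis (70.6 to 2.31 FPKM, -4.44), and the metabotropic glutamate receptor Grm4 (-4.27). The group also held the activity-regulated genes Arc (-4.26), Fosb (-4.19) and Egr1 (-3.83) and the RNA splicing factor Cwc22 (-4.11). The neuropeptide precursor Trh (-4.01), Syt6 of the synaptotagmin family (-3.93), the R-spondin receptor Lgr5 (-3.90) and the calmodulin-binding protein Nrgn (-3.89) completed this group. Their limma adjusted p ranged from 0.000268 to 0.0226. The Cwc22 libraries differed widely within each genotype, at 155 and 315 FPKM in the controls and 4.98 and 26.8 in DCKO. The largest increase was in Sprr1a, a small proline-rich protein that injured neurons are known to express, from 0.111 and 0.225 FPKM in the controls to 77.7 and 27.6 in DCKO (log2 change 5.35, SE 0.47, adjusted p = 0.00396). Cd52, a surface glycoprotein of immune cells (2.50), the vesicle release sensor Doc2b (2.39), and the cytokine Tnfsf11 (1.99) rose as well. The natriuretic peptide receptor Npr3 (1.95), Hyi, annotated in GENCODE as a polymorphic pseudogene (1.95), the potassium channel subunit Kcng1 (1.94) and the transcriptional regulator Prdm8 (1.94) also rose. The rule also named Hba-a1 (2.20), Hbb-b2 (2.09), Hist2h2aa2 (2.74) and Rpph1 (1.99), which are uncertain. The first 3 have near-identical copies, and Hist2h2aa2 was listed at close to 0 in both controls. The noncoding Rpph1, listed at 0 in control replicate 1, lost its call without DCKO replicate 1 (adjusted p = 0.123).

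Fewer genes were called in each direction when any library was left out, control or DCKO. Without control replicate 1, 1163 genes rose and 1022 fell, and without control replicate 2, 802 rose and 1030 fell, in fits where the lone control was assumed to vary like the DCKO pair. A split of 4 libraries into groups of 2 cannot give an exact permutation p below 0.333 for any single gene, and 71.5% of the tested genes had groups that did not overlap, against 33.3% by chance.

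Transcription factors of the bulb interneuron lineage fell together. Of the 15 measured members of this list, 12 fell and 1 rose, the same counts adjusted over the list alone, with a median log2 change of -1.73. The homeobox genes Meis2 (82.8 ± 0.747 FPKM in controls and 9.53 ± 2.79 in DCKO, SD, n = 2 per group, log2 change -3.02, limma adjusted p = 0.00172) and Pbx3 (58.5 ± 2.40 FPKM in controls and 12.2 ± 3.37 in DCKO, -2.20, adjusted p = 0.00326) fell. Dlx1, another homeobox gene, fell from 84.1 ± 0.962 to 19.7 ± 7.83 FPKM (-2.10, adjusted p = 0.00848). So did Tshz1, a zinc finger homeobox gene needed for bulb interneuron migration (chromosome 18, 84011627 to 84087706, - strand), which went from 65.0 ± 0.866 to 9.50 ± 1.10 FPKM (log2 change -2.66, adjusted p = 0.000742). Pax6 (-0.18) did not pass the test. Dlx6os1, counted in the list, is antisense to Dlx6, and their values cannot be separated where the strand setting is not given. The list was lower as a set by camera with a preset correlation (adjusted p = 2.60e-05 over 29 lists). The call was lost with an estimated correlation between genes (adjusted p = 0.509 with an estimated correlation). No list call held with an estimated correlation, with all 4 libraries or with 1 left out, so that p follows the camera calls below. This setting had little power with 4 libraries: the lowest unadjusted camera p of any list was 0.0515, for immediate early genes. The estimated correlation of the interneuron transcription factors was 0.731, far above the preset 0.01, so their preset p may be too small. Genes of GABA synthesis and transport missed too (unadjusted camera p = 0.0550), though their estimated correlation (-0.00669) was below the preset 0.01. A lost call alone therefore does not show that correlation between genes explains the preset call.

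The listed genes of GABA synthesis and transport and the measured markers of granule cells, the main interneuron class of the bulb, were lower without exception. All 5 genes of GABA synthesis and transport fell, in the test over all genes and adjusted over the list alone. Their median log2 change was -1.35 (camera adjusted p = 0.000257, and adjusted p = 0.386 with an estimated correlation). The vesicular GABA transporter Slc32a1 fell 8.14-fold (111 ± 1.98 FPKM in controls and 13.6 ± 2.67 in DCKO, SD, n = 2 per group, log2 change -2.95, limma adjusted p = 0.000959). The GABA-synthesising enzymes Gad1 (165 ± 42.4 FPKM in controls and 24.6 ± 8.92 in DCKO, -2.72, adjusted p = 0.00622) and Gad2 (-1.35, adjusted p = 0.0181) fell as well. All 8 measured granule cell markers fell too, likewise adjusted over the list alone. Their median was -1.83 (camera adjusted p = 2.12e-06, and adjusted p = 0.386 with an estimated correlation). Among them were the enkephalin precursor Penk (45.8 ± 0.592 FPKM in controls and 2.86 ± 1.23 in DCKO, log2 change -3.64) and the synaptic vesicle protein Synpr (190.1 ± 11.99 FPKM in controls and 21.5 ± 4.47 in DCKO, -3.10). The others of largest change were the G protein subunit Gng4 (-2.54) and Stxbp6 (-1.84), with limma adjusted p of 0.00111 to 0.00358.

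Genes that mark periglomerular classes changed to different degrees in whole-bulb RNA. Such RNA does not show which cells hold a transcript, and no test compared the classes. Markers of dopaminergic periglomerular cells fell for 3 of 5 measured genes, in both adjustments. Th (chromosome 7, 142892752 to 142931128, - strand) went from 70.6 ± 7.35 to 2.31 ± 0.573 FPKM, 30.5-fold lower (SD, n = 2 per group, log2 change -4.44, SE 0.15, limma adjusted p = 0.000709). The orphan nuclear receptor Nr4a2 fell from 11.2 ± 0.9998 to 0.659 ± 0.0735 FPKM (-2.88, adjusted p = 0.000745). The decarboxylase Ddc had a smaller decrease (-0.50, adjusted p = 0.0412). Slc6a3 (-0.69) and Slc18a2 (0.29), the dopamine and vesicular monoamine transporters, did not pass the test. Calb2, the calretinin gene that marks the most numerous periglomerular class, showed no detectable difference, at 293 ± 2.29 FPKM in controls and 296 ± 17.1 in DCKO (log2 change 0.01, 95% confidence interval -0.18 to 0.21, adjusted p = 0.906). Its sign turned with quantile normalization (-0.06). Of the 8 measured calcium-binding proteins and neuropeptides of interneurons, 3 fell, or 4 adjusted over the list alone, and 1 rose in both. Trh (31.1 ± 1.69 FPKM in controls and 1.06 ± 0.760 in DCKO, log2 change -4.01), Vip (-2.06) and Sst (-1.35, adjusted p = 0.0429) fell and Npy rose (0.74, adjusted p = 0.0163). Calb1, the calbindin gene, stood at 1.69 ± 0.309 and 2.35 ± 1.09 FPKM (adjusted p = 0.430). Pvalb lay below the filter, at 0.158 and 0.294 FPKM in the controls and 0.380 and 0.355 in DCKO. The dopaminergic list was lower as a set by camera (adjusted p = 0.0284, and adjusted p = 0.386 with an estimated correlation). This call was also lost with no filter (camera adjusted p = 0.0674) and on scaled counts (0.072). Without DCKO replicate 2 it was lost as well, with a list median of -0.47. The calcium-binding and neuropeptide list did not pass with all 4 libraries (camera adjusted p = 0.276, and 0.761 with the filter at a mean of 5 FPKM). It passed by fry (adjusted p = 0.0484), and otherwise only by preset camera without control replicate 1, where its median was -0.64. Single calls lost without 1 library were those of Ddc, for each of the 4 (highest adjusted p = 0.182, without control replicate 2), and Sst, without DCKO replicate 1 (adjusted p = 0.153) or 2 (0.0997).

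**Figure D1:**
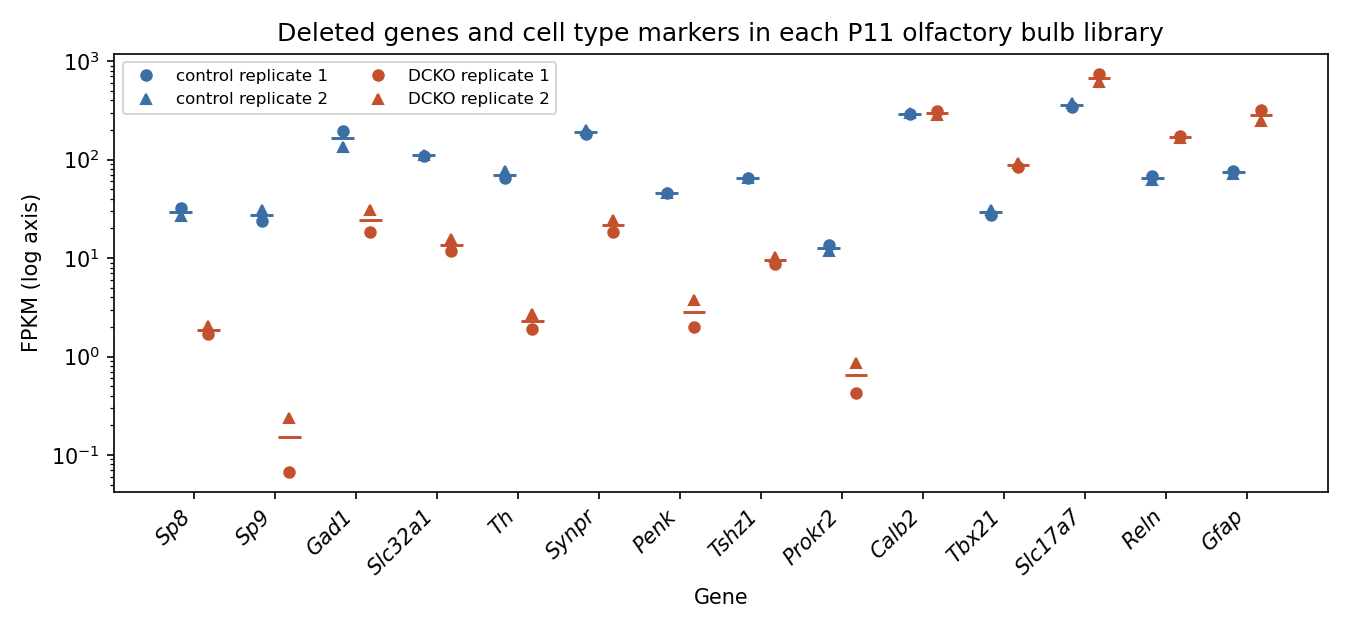
FPKM (log axis) of the deleted genes and 12 markers in each library, with controls in blue and DCKO in red, circles for replicate 1, triangles for replicate 2 and a line at the mean of each group. Calb2 sits at 284 to 308 FPKM in all 4 libraries, while Th falls from a mean of 70.6 to 2.31 FPKM and Tbx21 rises from 29.1 to 88.6 FPKM.

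Genes of neuroblast migration moved in both directions. Of the 20 measured members, 7 fell and 3 rose, or 8 and 5 adjusted over the list alone. Prokr2, the prokineticin receptor that guides neuroblasts into the bulb (chromosome 2, 132337733 to 132385447, - strand), fell 19.9-fold, from 12.8 ± 1.26 to 0.642 ± 0.307 FPKM (SD, n = 2 per group, log2 change -3.08, limma adjusted p = 0.00119). The neuregulin receptor Erbb4 (-1.23, adjusted p = 0.00845) and the reelin receptor Lrp8 (-1.07, adjusted p = 0.00483) fell, while Reln itself rose (65.3 ± 4.08 FPKM in controls and 169 ± 4.87 in DCKO, 1.35, adjusted p = 0.00126). The Slit receptor gene Robo1 stood at 7.25 ± 0.778 and 8.47 ± 0.158 FPKM and did not pass the test (log2 change 0.20, 95% confidence interval -0.05 to 0.45, adjusted p = 0.176). Among 9 immature neuron markers, 3 fell and 2 rose, or 5 and 2 adjusted over the list alone. Dcx, the microtubule protein of migrating neuroblasts, fell from 85.5 ± 0.832 to 19.6 ± 6.11 FPKM (-2.10, adjusted p = 0.00486), as did Igfbpl1 (-0.91) and Cd24a (-0.89). Stmn2 (0.82) and Dpysl3 (0.57), microtubule-associated proteins of growing axons, rose. Neither list passed as a set (camera adjusted p = 0.469 and 0.447). Without DCKO replicate 2, 6 of the immature neuron markers fell, and the Cd24a call was lost without control replicate 2 (adjusted p = 0.0879) or DCKO replicate 1 (0.0558).

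Mitral and tufted cells are the glutamatergic projection neurons of the bulb, and their markers were higher in DCKO. Of 10 measured markers, 8 rose and 1 fell, the same adjusted over the list alone. The median log2 change was 1.10 (camera adjusted p = 0.000201, and adjusted p = 0.386 with an estimated correlation). Tbx21, a T-box factor restricted to these cells in the bulb, rose 3.05-fold (29.1 ± 2.36 FPKM in controls and 88.6 ± 5.48 in DCKO, SD, n = 2 per group, log2 change 1.58, SE 0.09, limma adjusted p = 0.00130). The neuropeptide Nts (1.497), Reln (1.35) and the T-box factor Tbr1 (1.23) rose, as did the vesicular glutamate transporter Slc17a7 (362 ± 24.5 FPKM in controls and 682 ± 86.3 in DCKO, 0.91, adjusted p = 0.00924). Against the direction of the list, Cck, a peptide of tufted cells, fell (-0.61, adjusted p = 0.0185), and Doc2g did not pass the test (-0.15). The Cck call was lost without control replicate 2 (adjusted p = 0.0608) or DCKO replicate 1 (0.0661).

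Most ionotropic glutamate receptor subunits and immediate early genes were lower in DCKO, and GABA-A receptor subunits were mixed. Of 15 ionotropic glutamate receptor subunits, 10 fell and 2 rose, or 11 and 2 adjusted over the list alone. The median log2 change was -0.95 (camera adjusted p = 0.00148, and adjusted p = 0.386 with an estimated correlation). The NMDA receptor subunits Grin2d (17.5 ± 1.67 FPKM in controls and 3.37 ± 0.817 in DCKO, SD, n = 2 per group, -2.09), Grin2b (-1.36) and Grin2a (-1.23) and the AMPA receptor subunit Gria4 (-1.31) fell, with limma adjusted p of 0.00257 to 0.00748. Grik1 (0.9995) and Grin3a (0.91) rose. GABA-A receptor subunits split into 5 that fell, led by Gabra5 (-3.06) and the extrasynaptic subunit Gabrd (-2.22), 2 that rose and 5 of 12 that did not pass, the same adjusted over the list alone. Gabrb1 (0.50) and Gabrg1 (0.45) were the subunits that rose. Neither call held without control replicate 1 (adjusted p = 0.0968 and 0.134) or 2 (0.0649 and 0.128), nor did that of Gabrb1 without DCKO replicate 1 (0.0623) or that of Gabrg1 without DCKO replicate 2 (0.0787). That list did not pass as a set (camera adjusted p = 0.107), but did without control replicate 1 (adjusted p = 0.0204, and adjusted p = 0.468 with an estimated correlation) and by fry (adjusted p = 0.0415). The immediate early genes, whose transcription follows neuronal activity, had the lowest median of any list in the main fit. On scaled counts their median (-3.76) was above that of the sex-linked genes (-5.06). Of the 12 immediate early genes, 11 fell and none rose, the same adjusted over the list alone. Their median was -3.31 (camera adjusted p = 2.48e-09, and adjusted p = 0.386 with an estimated correlation). Arc (98.0 ± 16.8 FPKM in controls and 4.31 ± 1.90 in DCKO, -4.26), Fosb (30.0 ± 1.52 FPKM in controls and 0.701 ± 0.238 in DCKO, -4.19), Egr1 (149.8 ± 11.7 FPKM in controls and 9.69 ± 2.27 in DCKO, -3.83) and Egr4 (-3.78) fell the most, with limma adjusted p of 0.000639 to 0.00185. Jun was the member that did not pass, at 28.1 ± 3.78 and 25.2 ± 3.02 FPKM (log2 change -0.15, adjusted p = 0.412).

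**Figure D2:**
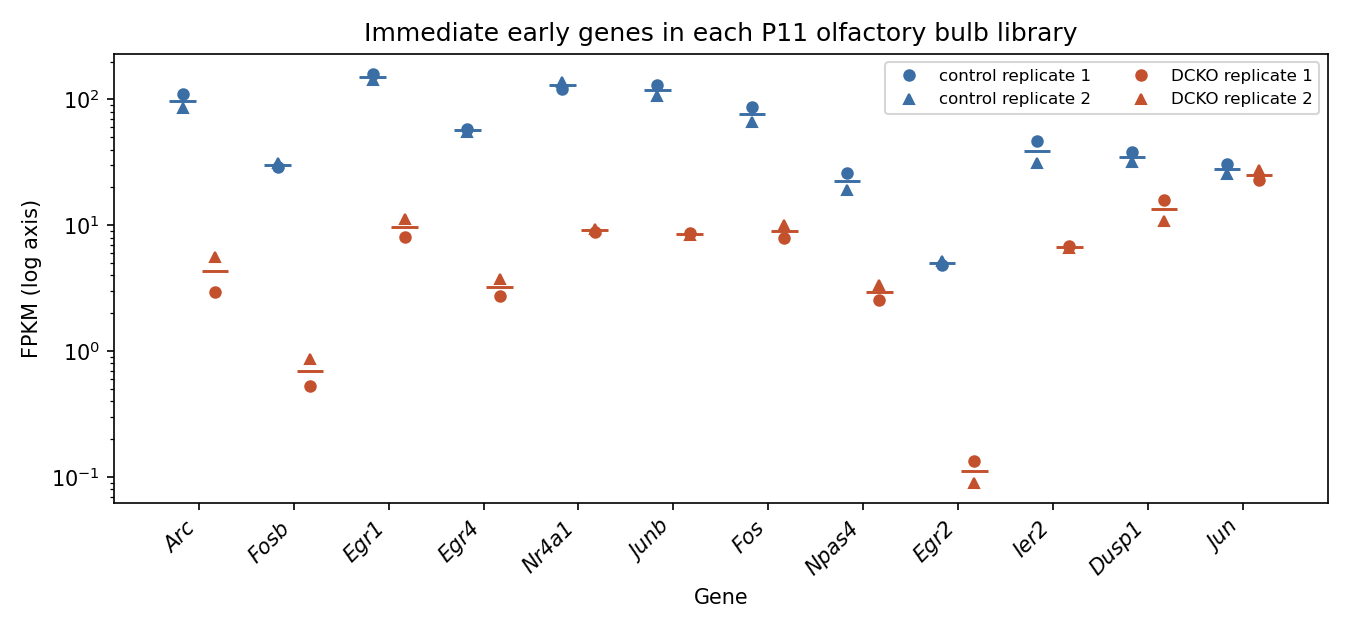
FPKM (log axis) of the 12 immediate early genes in each library, with controls in blue and DCKO in red, circles for replicate 1, triangles for replicate 2 and a line at the mean of each group. Both DCKO libraries lie below both controls for the 11 genes that fell, and Jun overlaps, with means of 28.1 and 25.2 FPKM.

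Genes of dividing cells were higher in DCKO. Of 11 cell cycle genes, 9 rose, or 10 adjusted over the list alone, and none fell. The median log2 change was 0.85 (camera adjusted p = 3.19e-05, and adjusted p = 0.442 with an estimated correlation). The topoisomerase Top2a (3.40 ± 0.387 FPKM in controls and 7.92 ± 1.52 in DCKO, SD, n = 2 per group, 1.01, limma adjusted p = 0.0127), cyclin Ccnb1 (0.98), Birc5 (0.94) and the proliferation marker Mki67 (0.92) rose. Of 8 neural progenitor markers, 3 rose, or 5 adjusted over the list alone, and none fell. The growth factor receptor Egfr (0.71) and the Notch effector Hes5 (0.63) were among those that rose. This list passed as a set (camera adjusted p = 0.0163, and adjusted p = 0.386 with an estimated correlation), but not without DCKO replicate 2 (adjusted p = 0.0518) or with the filter at a mean of 5 FPKM (0.114). The Egfr call was lost without control replicate 2 (adjusted p = 0.0634) and that of Hes5 without control replicate 1 (0.0717). Among 8 p53 target and cell death genes, the cyclin Ccng1 rose (0.56, adjusted p = 0.00772). The death effector Bax (-0.36) and the p53 regulator Mdm2 (-0.31) fell, and 5 did not pass. Adjusted over the list alone, 2 rose and 3 fell, and the list did not pass as a set (camera adjusted p = 0.955). Its camera direction was negative, while its median of 0.03 and its fry direction were positive. The calls of Bax and Mdm2 were lost without control replicate 1 (adjusted p = 0.119 and 0.142), control replicate 2 (0.0861 and 0.235) or DCKO replicate 1 (0.0542 and 0.0857), and that of Mdm2 also without DCKO replicate 2 (0.0522).

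Markers of neuron types from neighbouring forebrain regions were mixed. Of 4 measured genes of medial ganglionic eminence and cortical interneurons, 2 rose, among them Sox6 (0.97, limma adjusted p = 0.00849). Maf and Satb1 did not pass, and Nkx2-1, Lhx6 and Lhx8 lay below the filter. Of this list, 1 rose without control replicate 1, control replicate 2 or DCKO replicate 2. Of 8 striatal neuron markers, 3 fell and 1 rose. Foxp2 (-1.19), Bcl11b (-0.75) and Adora2a (-0.46) fell. Ppp1r1b, which encodes DARPP-32, rose 3.33-fold (17.9 ± 0.868 FPKM in controls and 59.8 ± 9.88 in DCKO, SD, n = 2 per group, 1.67, adjusted p = 0.00267). Of 6 cortical excitatory neuron markers, Neurod2 (1.63, adjusted p = 0.0195) and Emx1 (0.92, adjusted p = 0.0345) rose and the other 4 did not pass. Adjusted over the list alone 3 rose, while the counts for the other lists of this paragraph were the same in both adjustments. None passed as a set (camera adjusted p = 0.107, 0.276 and 0.224). The Adora2a call was lost without any 1 of the 4 libraries (highest adjusted p = 0.197, without control replicate 2). The call of Neurod2 was lost without DCKO replicate 1 (adjusted p = 0.0578), and that of Emx1 without DCKO replicate 1 (0.104) or 2 (0.113). Rasgrf2 was called lower without DCKO replicate 1 (log2 change -2.26, adjusted p = 0.00779), where no cortical marker was called higher, and without DCKO replicate 2 (-0.58, adjusted p = 0.0229), where 2 were.

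Astrocyte and microglia transcripts were higher in DCKO, where red blood cell transcripts were higher too (Alas2 at 8.88 and 11.6 FPKM against 2.27 and 1.85 in the controls). Of 12 astrocyte markers, 7 rose and 1 fell, or 9 and 1 adjusted over the list alone. The median log2 change was 0.59 (camera adjusted p = 0.000430, and adjusted p = 0.386 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose 3.77-fold (74.6 ± 3.91 FPKM in controls and 282 ± 49.8 in DCKO, SD, n = 2 per group, 1.89, limma adjusted p = 0.00241). The water channel Aqp4 (1.08) and the connexins Gjb6 (0.92) and Gja1 (0.89) rose, while the GABA transporter Slc6a11 fell (-0.32), a call lost without control replicate 1 (adjusted p = 0.153) or 2 (0.180). Of 7 reactive glia genes, 5 rose, among them Vim (0.92), S1pr3 (0.73) and Osmr (0.64). Adjusted over the list alone, 6 rose (camera adjusted p = 0.00142, and adjusted p = 0.485 with an estimated correlation). Without control replicate 2, DCKO replicate 1 or DCKO replicate 2, 3 of them rose, and the Osmr call was lost in each of these (highest adjusted p = 0.0906, without control replicate 2). Of 12 microglia markers, 9 rose in both adjustments (median 0.62, camera adjusted p = 0.000224, and adjusted p = 0.386 with an estimated correlation). They were led by the complement gene C1qb (13.3 ± 1.24 FPKM in controls and 32.1 ± 1.18 in DCKO, 1.22), Trem2 (0.996), C1qc (0.91) and C1qa (0.90). P2ry12 (-0.03) and Itgam (-0.04) did not pass, nor did Tmem119, and the C1qc call was lost without DCKO replicate 1 (adjusted p = 0.0551). Markers of olfactory ensheathing cells, the glia of the olfactory nerve layer, rose for 4 of 7 genes in both adjustments (camera adjusted p = 0.00385, and adjusted p = 0.386 with an estimated correlation). These were Ngfr (0.84), Npy (0.74), Frzb (0.58) and Fabp7 (0.58). Fabp7 lost its call without control replicate 1 (adjusted p = 0.205) or 2 (0.211), and with quantile normalization, where its log2 change was 0.13 (adjusted p = 0.349).

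None of 9 oligodendrocyte and 6 oligodendrocyte precursor markers passed in either adjustment, and neither list passed as a set (camera adjusted p = 0.579 and 0.280). Myelin transcripts differed between the DCKO libraries, with the myelin protein gene Mbp at 444 and 174 FPKM against 265 and 394 in the controls. The precursor genes Olig1 (0.13, limma adjusted p = 0.461) and Sox10 (0.25, adjusted p = 0.186) did not pass. The camera direction of the oligodendrocyte list was positive and its median was -0.16. Without DCKO replicate 2, the library with the lower myelin values, both lists were higher as a set (camera adjusted p = 0.0115 and 0.0257, and adjusted p = 0.627 and 0.679 with an estimated correlation). Without DCKO replicate 1 the camera direction of both lists was negative and neither passed (adjusted p = 0.202 and 0.977), with 1 oligodendrocyte marker called lower.

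Vascular, meningeal and blood transcripts were higher in part. Of 10 endothelial and pericyte markers, 3 rose, or 7 adjusted over the list alone, and none fell (camera adjusted p = 0.00405, and adjusted p = 0.386 with an estimated correlation). The organic anion transporter Slco1a4 of the blood-brain barrier (1.005, limma adjusted p = 0.00852), the tight junction gene Cldn5 (0.37) and the pericyte receptor Pdgfrb (0.45) rose. Without control replicate 1 or 2, 1 of the markers rose, and both Cldn5 (adjusted p = 0.0831 and 0.124) and Pdgfrb (0.0715 and 0.121) lost their calls, the latter also without DCKO replicate 2 (0.0555). Of 8 meningeal fibroblast markers, the GABA transporter Slc6a13 (1.01) and the prostaglandin synthase Ptgds (1.23) rose, or 4 adjusted over the list alone (camera adjusted p = 0.0883). Without control replicate 1, whose bone and collagen transcripts were high, 7 of them rose and the list was higher as a set (camera adjusted p = 1.94e-05, and adjusted p = 0.468 with an estimated correlation). Without control replicate 2, 1 of them rose and 2 fell (camera adjusted p = 0.724). Ptgds lost its call without control replicate 2 (adjusted p = 0.0657), DCKO replicate 1 (0.0964) or DCKO replicate 2 (0.0775). Of 6 red blood cell genes, 3 rose in both adjustments (median 1.72, camera adjusted p = 0.00646, and adjusted p = 0.386 with an estimated correlation). Both DCKO libraries had more of them, with Hba-a1 at 1219.8 and 1685 FPKM against 493 and 196, and the heme synthesis gene Alas2 at 8.88 and 11.6 against 2.27 and 1.85 (log2 change 1.87, adjusted p = 0.00321). Hba-a1 lost its call without DCKO replicate 1 (adjusted p = 0.0768) or 2 (0.0996), and 5 of the blood genes rose without control replicate 1. Choroid plexus and ependyma markers were not tested as a list, since 2 members passed the filter.

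The libraries also differed in ways that the genotypes do not describe. Control replicate 1 held more transcripts typical of nasal tissue and bone. The summed FPKM of 817 olfactory receptor genes was 162 there and 13.9, 17.99 and 13.2 in control replicate 2, DCKO replicate 1 and DCKO replicate 2. The secreted airway protein gene Bpifa1 stood at 68.3 against 0.549 FPKM in the other control and the bone matrix genes Ibsp at 15.6 against 0.804 and Col1a1 at 121 against 17.6. Omp, the marker of mature olfactory sensory neurons, stood at 98.4 against 20.1, 31.5 and 20.3 FPKM. None of 7 olfactory sensory neuron markers passed in either adjustment (median log2 change -1.001, camera adjusted p = 0.303). Without control replicate 2, which leaves control replicate 1 as the lone control, 6 fell, Omp among them (log2 change -1.92, limma adjusted p = 0.00331). The list was then lower as a set (camera adjusted p = 1.89e-06, and adjusted p = 0.534 with an estimated correlation). The signalling subunit Gng13 stood at 106 ± 53.8 and 132 ± 19.3 FPKM (SD, n = 2 per group), and rose without control replicate 1 (log2 change 0.94, adjusted p = 0.0114). DCKO replicate 1 was the library that expressed Xist, at 77.0 FPKM, and it was listed at 0 for the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty. The other 3 libraries had Xist at 0.0252 to 0.0355 FPKM and Eif2s3y at 27.7 to 30.8 FPKM. By these genes DCKO replicate 1 was female and the others male, so sex was not balanced between the genotypes. None of the 5 sex-linked genes passed in either adjustment (camera adjusted p = 0.477), and without DCKO replicate 2, 4 fell and the set was lower (adjusted p = 0.0257, and adjusted p = 0.669 with an estimated correlation), with Xist higher (adjusted p = 0.00328). Leaving out all genes on chromosomes X and Y gave 1701 higher and 1870 lower genes.

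**Figure D3:**
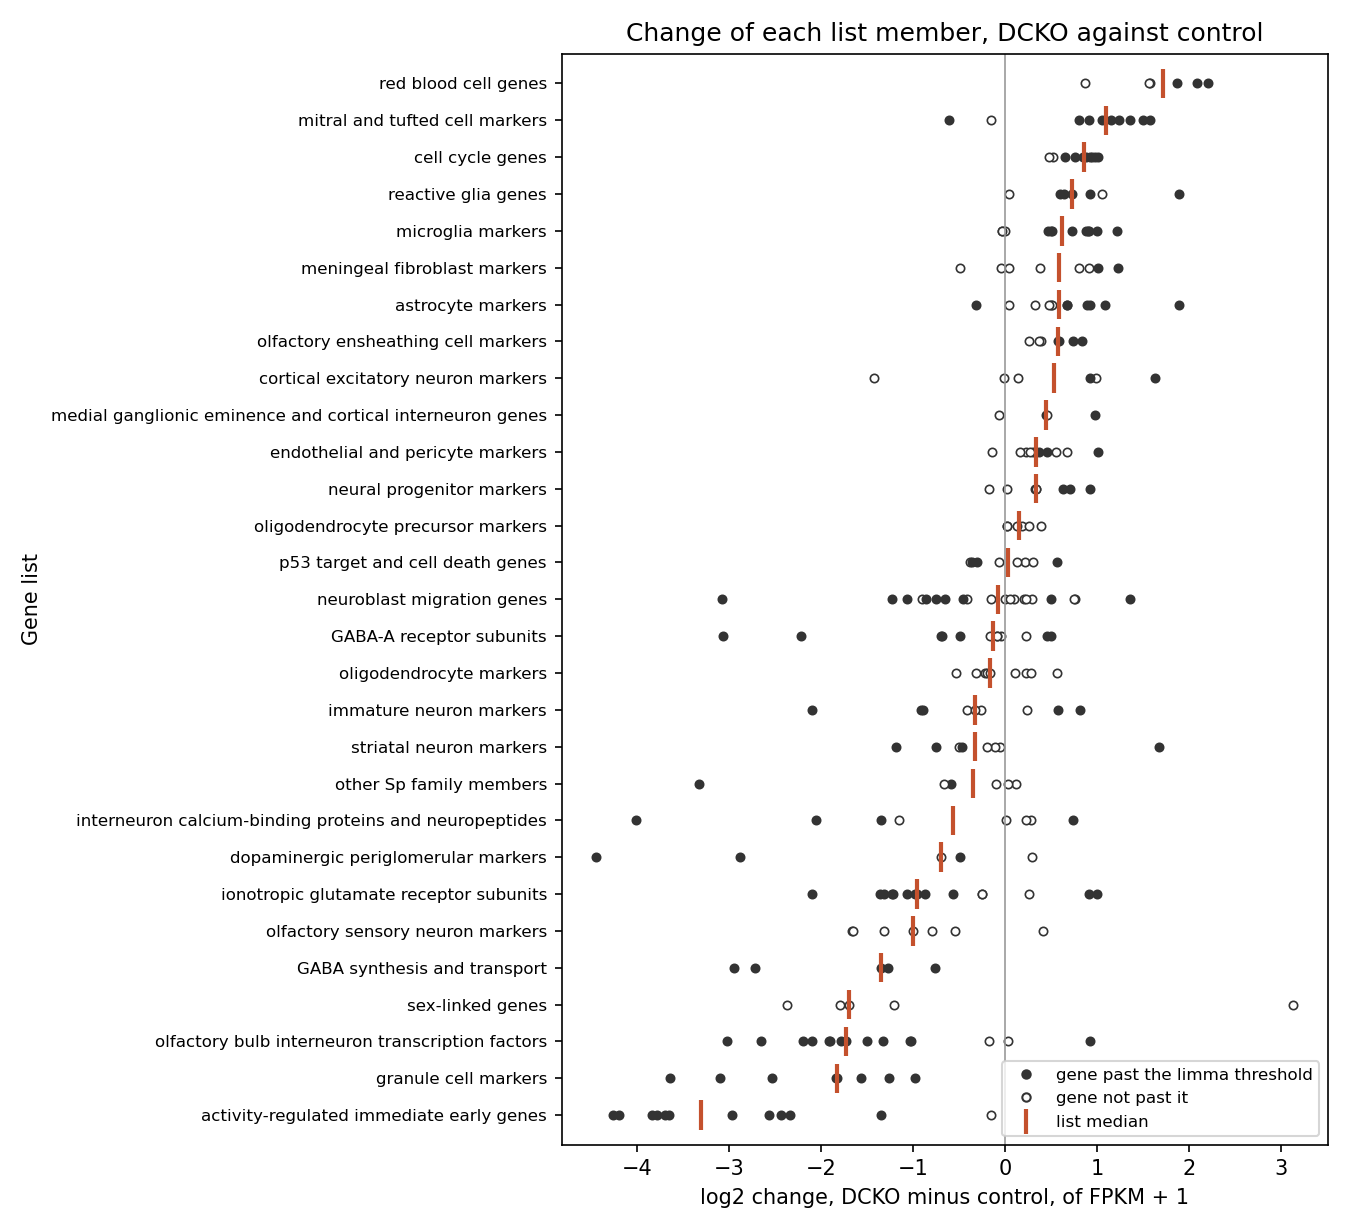
Log2 change of FPKM + 1, DCKO minus control, for every tested member of the 29 gene lists, with filled circles for genes past the limma threshold, open circles for the others and a red bar at each list's median. Medians run from -3.31 for immediate early genes to 1.72 for red blood cell genes, with granule cell markers at -1.83 and mitral and tufted cell markers at 1.10.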

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

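The fit on scaled counts and the fit without chromosomes X and Y were chosen after the data were seen; the other alternatives were planned. Count models were not run because the values are not raw counts, and no comparison table by the authors was used.

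Across all alternatives, 1709 values for named genes kept direction and side of the threshold, 87 fell below it, 5 rose past it and 9 changed sign. The list tests gave 475, 20, 9 and 14 in the same order. Camera fitted its own variance trend each time, so the fits with no trend and with a robust trend could not change a list test. Their outcomes are among the 475 and were fixed in advance. Sp8, Sp9, Th, Prokr2, Tshz1 and Tbx21 were called in the same direction under every alternative run. Under the other scalings the counts ran from 1688 higher and 2098 lower with equal sums to 1997 higher and 1755 lower with quantile normalization. With no filter on low values there were 1188 higher and 1434 lower genes, and on scaled counts 1960 and 2141. Of the 1747 higher and 1926 lower genes, 1033 and 1329 kept their call with no filter. With the replicate block 1234 and 1386 did, and with quantile normalization 1669 and 1693. Most named genes were chosen as the largest called changes, so their tally above does not measure how stable all calls are. All of these higher and lower genes kept their sign under the other scalings, except 1 higher gene under quantile normalization. The median log2 change over all genes moved only from -0.0272 with equal sums to 0.0155 with quantile normalization. These scalings could therefore hardly turn the sign of a called gene.

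At an adjusted p below 0.10, 2629 genes were higher, and with a log2 change of at least 1, 158 were higher and 410 lower. With each library left out in turn, 802 to 1387 were higher and 1022 to 1910 lower. The lone sample of a genotype is assumed to vary like the other group. Of the 103 called named genes, 20 lost their call without 1 library, 17 with no filter, 4 under another scaling (Fabp7 with quantile normalization among them, adjusted p = 0.349) and 2 on scaled counts. Cwc22 lost its call with no filter (adjusted p = 0.0583) and with a robust trend (0.0715). Gabrb1 (0.0502), Gabrg1 (0.0791) and Slc6a11 (0.0535) lost theirs with no filter. The causes were not tested.

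With an estimated correlation, no camera call held, but with 4 libraries that setting had little power (lowest unadjusted camera p 0.0515). Of the primary lists, GABA synthesis and transport, granule cell, mitral and tufted cell and dopaminergic markers went to a camera adjusted p of 0.386. Interneuron transcription factors, whose estimated correlation was 0.731, went to 0.509. The dopaminergic list also missed with no filter (0.0674) and on scaled counts (0.0724), and ranged over 0.00441 to 0.0581 with 1 library left out. The calcium-binding and neuropeptide list passed by fry (0.0484) and ranged over 0.0250 to 0.375 with 1 library left out. For these lists the cause was not tested.

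Among the named genes and lists, signs changed only for those not past the threshold. With 1 library left out, log2 changes ranged from -0.053 to 0.625 for Calb1, -0.045 to 0.072 for Calb2 (-0.059 with quantile normalization), -4.86 to 0.13 for Eif2s3y, -0.13 to 0.94 for Gng13, -0.89 to 0.46 for Mbp, -0.009 to 0.26 for Olig1 and -1.92 to 0.32 for Omp. Camera adjusted p ranged over 1.89e-06 to 0.610 for olfactory sensory neuron markers, 0.0115 to 0.796 for oligodendrocyte, 0.0257 to 0.977 for oligodendrocyte precursor, 0.0257 to 0.811 for sex-linked and 0.506 to 0.972 for p53 target genes. The p53 list also changed direction with a filter at a mean of 5 (0.920), fry (0.870), no filter (0.456), quantile normalization (0.967) and scaled counts (0.425), and migration genes did with a filter at a mean of 5 (0.305). The cause was not tested.

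The replicate numbers share only a number: same-numbered libraries deviated with a correlation of -0.0211 across genes. With the replicate block, 1312 genes were higher and 1418 lower, 9 named genes lost their call, the calls of Gabrg1 (0.0606) and Slc6a11 (0.0701) were lost, and the p53 list changed direction (adjusted p = 0.962). Depth limits genes of low value, and Pvalb, below the filter, was not tested.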

Other observations

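The tests on cell shares, scaling, the even loss of GABAergic neurons and linked alleles were chosen only after the results were seen. The predictions for the tests without control replicate 1 and on handling genes were written before those tests were run, but they address patterns already seen.

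The genes of this paragraph were chosen after their values were seen, and stand for no list or theme. The homeobox gene Meis1 (16.5 ± 0.0101 FPKM in controls and 0.687 ± 0.154 in DCKO, SD, n = 2 per group, log2 change -3.38, limma adjusted p = 0.000639), the corticotropin-releasing hormone receptor Crhr1 (-3.26), and the potassium channel Kcnh3 (-3.69) fell. The calmodulin regulators Pcp4 (-2.74) and Pcp4l1 (-3.56), and the calcium-binding protein Scgn (-3.17) also fell. The muscarinic receptor Chrm2 (-2.68), the adrenergic receptor Adra1d (-3.47), the VIP receptor Vipr2 (-1.98), and the metabotropic receptor Grm2 (-2.55) fell as well. The telencephalic adhesion molecule Icam5 (-2.71) and Rbfox3, which encodes the mature neuron antigen NeuN (-2.59), fell too. All of these had a limma adjusted p of 0.000268 to 0.00116. The HLH inhibitors Id3 (65.0 ± 4.67 FPKM in controls and 178 ± 3.26 in DCKO, 1.45) and Id4 (1.42), the prodynorphin gene Pdyn (1.77), the tachykinin Tac2 (1.53), Gnrh1, the gonadotropin-releasing hormone (1.38), and the homeobox gene Prox1 (1.66) rose, with adjusted p of 0.00119 to 0.0236. So did the phagocyte lysozyme Lyz2 (1.51) and the complement gene C4b (1.71). The Gnrh1 call was lost without DCKO replicate 1, where its log2 change was 1.06. The other genes named above kept their calls when 1 library was left out. Of further genes picked in the same way, Cd74, Hrk, Gpnmb and Il1f9 lost a call without 1 library. The genes named here are therefore no measure of how stable the calls are.

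Markers of mitral and tufted cells, astrocytes and microglia were higher in DCKO. The lowest mitral and tufted median under 4 scalings was 1.09. The FPKM sums were already close (344704 to 351233), so rescaling could hardly move this median. None of the scalings measured absolute RNA amounts, so a scaling effect stays undecided. Adhering tissue in control replicate 1 was argued against, as the mitral and tufted median without that library was 1.04. The tables argue, with less weight, against a lower share of interneurons that raises 7 other cell types by 1 common factor: their list medians spread over 1.26 log2 units (permutation p = 0.00083, 100000 resamples of 64 genes), from -0.16 for oligodendrocyte to 1.10 for mitral and tufted cell markers, but over 0.835 units without DCKO replicate 2 (permutation p = 0.0307), and a permutation of genes leaves out the spread between libraries. The narrower comparison of mitral and tufted with oligodendrocyte precursor markers, 0.948 apart, cannot be told apart from an equal rise, as its exact permutation p was 0.0589 over 8008 reassignments of genes. A lower share of interneurons combined with changes in single cell types, and a direct effect of the loss of Sp8 and Sp9, may both contribute and were not tested.

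Immediate early genes had the lowest median of the lists in the main fit. An even loss of GABAergic neurons in the share given by Slc32a1 was argued against, since 6 of the 12 genes (Arc, Egr1, Egr4, Fosb, Junb and Nr4a1) lay below the Slc32a1 change by more than 2 standard errors of the difference. That share is uncertain. The interneuron markers Penk (-3.64) and Th (-4.44) also fell further than Slc32a1 (-2.95), while Gad1 (-2.72) and Gad2 (-1.35) fell less. The test therefore cannot decide on a loss of interneurons in another share. A weaker response to handling cannot be told apart from none: 9 handling and stress genes had a median log2 change of -0.37 and went both ways, with Atf3, Hspa1b and Gadd45b lower and Klf6 higher. An uneven loss of the cells most active in the bulb, or lower activity per cell after the loss of Sp8 and Sp9, may each lower these genes and stay open, untested.

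Some called genes lie within 10 Mb of the floxed loci, among them Scrn3 (1.89, limma adjusted p = 0.00343), close to Sp9 on chromosome 2, and Cwc22 (-4.11), farther along it. A general effect of alleles linked to the floxed loci was argued against: within 10 Mb of Sp8 or Sp9, 41 of 143 tested genes were called (28.7%), against 27.4% elsewhere (odds ratio 1.07, 95% confidence interval 0.722 to 1.55, Fisher's exact p = 0.707 across genes). The sample titles name the controls as without Cre and do not give their Sp8 and Sp9 alleles. Whether linked alleles differed between the groups at all is therefore open. Strain alleles of the mixed background may still account for single genes such as Cwc22 and Scrn3 (odds ratio 1.07 covers the set, not each gene), which these tables leave open beside an effect of the deletion.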
